A study of Caenorhabditis elegans with 4 samples.

How the data were processed

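Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out with a rabbit polyclonal antibody against LIN-61 on third-stage (L3) larvae of the wild-type Caenorhabditis elegans strain N2, in populations of both males and hermaphrodites. LIN-61 is a chromatin protein with MBT repeats. Per the labels' protocols, larvae were grown in liquid culture, frozen and ground, and the chromatin was crosslinked with EGS and formaldehyde and sheared by sonication before immunoprecipitation. The series holds 2 ChIP libraries and 2 input DNA libraries. No processed file of the input libraries was at hand, so no comparison of ChIP with input was made. The background in the input was not measured. The labels number the libraries as replicates without saying whether they came from separate cultures, so the spread between the replicates may be technical.

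Reads were aligned with BWA to the ce10 genome, per the submitters' processing notes. Peaks were called with MACS on the WormBase WS220 genome, per the file headers, which is the assembly that ce10 denotes. The versions of BWA and MACS, the calling threshold, the filters, and whether the input served as the control in calling are not given in the sources used here. The authors deposited 1 peak list for each ChIP library and 1 list for the whole series. How the whole-series list was made is not stated, so its values are given as the authors' own, with no SD. Each list gives a start, an end and a score for each peak. The meaning of the deposited score is not stated. The lowest score in the 3 lists was 1.30, so that it may be a minus log10 of a q-value cut at 0.05, but it was treated as a score and used only to rank peaks within a list. No file states a read count, so the sequencing depth behind the peaks is unknown, and part of any difference in peak number between the replicates can come from depth. Intervals given for shares of peaks are exact (Clopper-Pearson) 95% binomial intervals. They cover counting error only and treat peaks as independent, which neighbouring peaks are not.

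Samples were grouped by their titles. The extent of each chromosome was taken as 1 to the last peak end in any list, which gave 100.3 Mb in all. Each chromosome was divided into 3 sections of equal length. The left and right sections are called the arms and the middle section the centre, and a peak belongs to the section that holds its midpoint. Positions are 1-based WS220 coordinates. Densities are peaks per Mb, given for each replicate or as the mean ± SD of the 2 replicates. Arms and centres were compared with the chromosome as the unit, by an exact two-sided sign-flip permutation test over the 6 chromosomes (64 sign patterns, so the smallest p is 0.03125). The same test was used for 1 arm of each chromosome, meant to hold the meiotic pairing centre, against the opposite arm. It took the right arm of I and IV and the left arm of II, III, V and X. The pairing centre lies at the right end of I and V and at the left end of II, III, IV and X, which is textbook knowledge. The test therefore took the opposite arm on IV and V and does not compare pairing-centre arms. Arm densities by the true ends are given without a test. Benjamini-Hochberg adjustment ran over the 5 chromosome-level tests. These were density, width and score of arms against centre, the arm taken as the pairing-centre arm against the other arm, and X against the autosomes.

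A peak counted as shared when it overlapped a peak of the other list by at least 1 bp. The shared percentage was compared with 10000 random circular shifts of the replicate 2 list along each chromosome, in a one-sided permutation test. Clustering was the percentage of peaks with another peak of the same list within 5 kb. It was compared with 1000 random non-overlapping placements of the same peak widths within the same section of the same chromosome, again in a one-sided permutation test. Score agreement was Spearman's rho across peaks, between the score of a peak and the highest score among the peaks of the other replicate that overlap it. The named peaks are the 10 with the highest score in the whole-series list among those overlapped in both replicates. The densest and sparsest section and the longest stretch shared by both replicates in which peaks lie less than 5 kb apart are named too.

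Alternatives were the higher-scoring 50% of each list, a reciprocal overlap of 50%, a midpoint rule for overlap, arms as the outer 25% at each end, covered bases in place of peak number, merging of peaks less than 500 bp apart, clustering distances of 1 kb and 20 kb, each replicate left out in turn, and the whole-series list. These choices, the tests and the naming rule were fixed before the data were examined. Random placement within sections as a second chance model for the overlap, merged peak numbers, and stricter overlap rules for the named peaks were added after seeing the data. The planned assignment of peaks to genes, repeats and gene lists was not run: the gene table at hand is for the WBcel235 assembly, and coordinates of different assemblies were not mixed.

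The functions were tested on simulated lists of 9958 peaks, the number in replicate 1. A simulated arm-to-centre fold of 3 came out as 2.905. A list made of 60% of the peaks of another gave a shared percentage of 59.992. Its peaks had the same edges, so this does not check overlap between lists whose peak edges differ. A list without clustering gave a clustering excess of -0.608 percentage points. Among 100 simulated lists of 2000 peaks with no arm effect, the sign-flip test called 4%. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.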

Results

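LIN-61 binding was mapped in wild-type L3 larvae in 2 ChIP libraries, and the series also holds 2 input DNA libraries that were not analysed here. LIN-61 belongs to the synMuv B class of C. elegans genes, which act in chromatin-based repression. The replicate 1 list held 9958 peaks covering 4.32 Mb, or 4.30% of the genome. The replicate 2 list held 13486 peaks covering 7.23 Mb, or 7.21%. The median peak width was 278 bp in replicate 1 and 313 bp in replicate 2, and the widest peaks spanned 8945 bp and 15378 bp. The authors' list for the whole series held 14662 peaks covering 8.97 Mb, with a median width of 339 bp. Read depth was unknown for each of these lists.

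The first comparison asked where along the chromosomes LIN-61 peaks lay. Peaks were concentrated on the chromosome arms, the repeat-rich outer parts of C. elegans chromosomes, and were sparse in the gene-dense centres. The arms, which are 2 of the 3 equal sections of each chromosome, carried 86.7% ± 0.8 of the peaks (SD, n = 2). They held 89.0% ± 1.3 of the bases in peaks. Over the genome, peak density was 152 ± 31 per Mb on the arms and 46.9 ± 13 per Mb in the centres (SD, n = 2), a 3.27 ± 0.23-fold difference. By covered bases the difference was 4.08 ± 0.55-fold.

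Chromosome III showed the strongest arm bias, with 253 ± 27 peaks per Mb on its arms and 66.1 ± 16 in its centre. The difference was 3.89 ± 0.51-fold (SD, n = 2). In replicate 1 the next chromosome by this fold was IV (4.251-fold on III against 3.623-fold). In replicate 2 it was I, and the lead of III was slight (3.53-fold against 3.51-fold). On chromosome I the arms held 225 ± 50 peaks per Mb against 66.9 ± 10 in the centre. Chromosome IV had 161 ± 25 against 48.6 ± 13, and chromosome II had 148 ± 36 against 46.2 ± 13. Chromosome V had 121 ± 31 against 42.1 ± 17. The X chromosome had the smallest arm bias, with 41.3 ± 19 against 19.4 ± 7.8 peaks per Mb, a 2.10 ± 0.15-fold difference. Averaged over chromosomes, the arms exceeded the centre by 110.1 peaks per Mb, by 96.9 in replicate 1 and by 123.3 in replicate 2, and the difference had the same sign on 6 of 6 chromosomes in both replicates. The exact sign-flip permutation test gave p = 0.03125, the smallest value that 6 chromosomes allow. Adjusted over the 5 chromosome-level tests it was 0.052, so the contrast did not pass 0.05 after adjustment. The adjusted value follows from how many of the 5 tests stood at that smallest p, and the X test could not have passed. It therefore does not measure the size of the contrast. The difference was 64.3 peaks per Mb once peaks less than 500 bp apart were merged, where the fold over the genome was 2.95 ± 0.16, and 64.7 in the higher-scoring 50% of each list, where the fold was 4.56 ± 0.38.

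**Figure D1:**
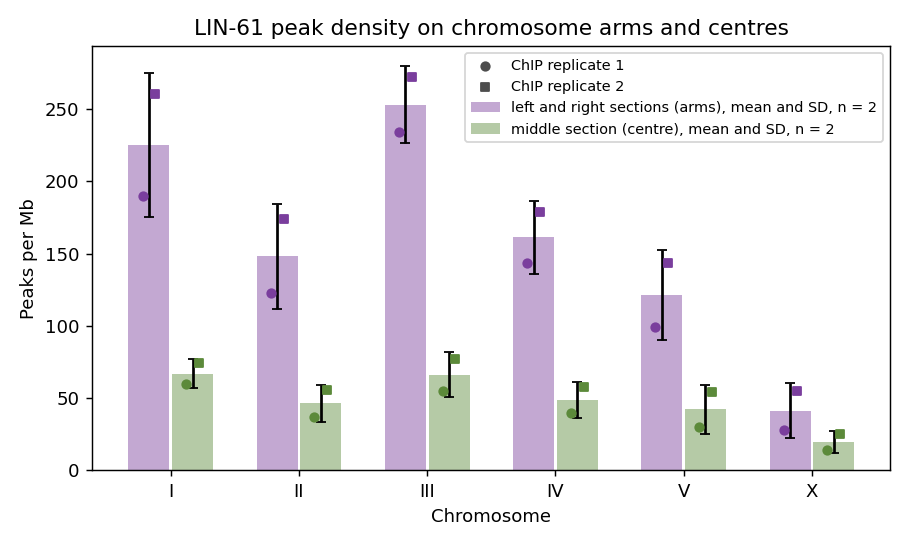
LIN-61 peaks per Mb (y axis) on the arms (left and right sections, purple) and the centre (middle section, green) of each chromosome (x axis). Bars are the mean of the 2 ChIP replicates, error bars their SD, and points the single replicates; arm bars stand above centre bars on each of the 6 chromosomes, with the highest arm value on III (253 per Mb) and the lowest on X (41.3 per Mb).

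Peaks on the arms were also wider and scored higher within their list. The median width was 301.6 bp on the arms and 256.2 bp in the centres, averaged over chromosomes and replicates. The difference of 45.4 bp was positive on 6 of 6 chromosomes, and was 45.6 bp in replicate 1 and 45.2 bp in replicate 2. It was largest on chromosome III in both replicates, at 86.8 ± 13 bp (SD, n = 2). The median score stood at percentile 51.4 of its list on the arms and at percentile 39.0 in the centres. The difference of 12.5 ± 0.6 percentile points (SD over 2 replicates) was again positive on 6 of 6 chromosomes. Many scores were tied, with 1187 distinct scores among the 9958 peaks of replicate 1. In that replicate the difference was the same on I and X, at 5.87 percentile points. The width and score contrasts both had p = 0.03125 in the exact sign-flip permutation test, and an adjusted value of 0.052. The width difference was 89.3 bp in the higher-scoring 50% and 107.5 bp after merging.

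The sections differed widely in density. The left arm of chromosome III (positions 1 to 4594566) had the highest mean density of the 18 sections, with 283 ± 14 peaks per Mb (SD, n = 2), and peaks covered 15.5% of it in replicate 1 and 19.6% in replicate 2. The left arms of I and IV came next by mean density, with 250.1 ± 63 and 229 ± 20 peaks per Mb. The order of the first pair was not stable: the left arm of I was slightly above that of III in replicate 2 (294.8 against 292.5) and above it in the authors' whole-series list (323.8 against 301.4). The centre of X (positions 5906289 to 11812577) was the sparsest, with 19.4 ± 7.8 peaks per Mb and 0.50% and 1.17% of its bases covered. Chromosome IV was lopsided: its right arm held 93.2 ± 30 peaks per Mb, less than its left arm in both replicates (71.7 against 215 in replicate 1, and 115 against 243 in replicate 2). On chromosome V the right arm was the denser, with 148 ± 24 against 94.6 ± 38 on the left. Differences between single sections were not tested; with 2 replicates a permutation test cannot reach a p under 0.05.

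**Figure D2:**
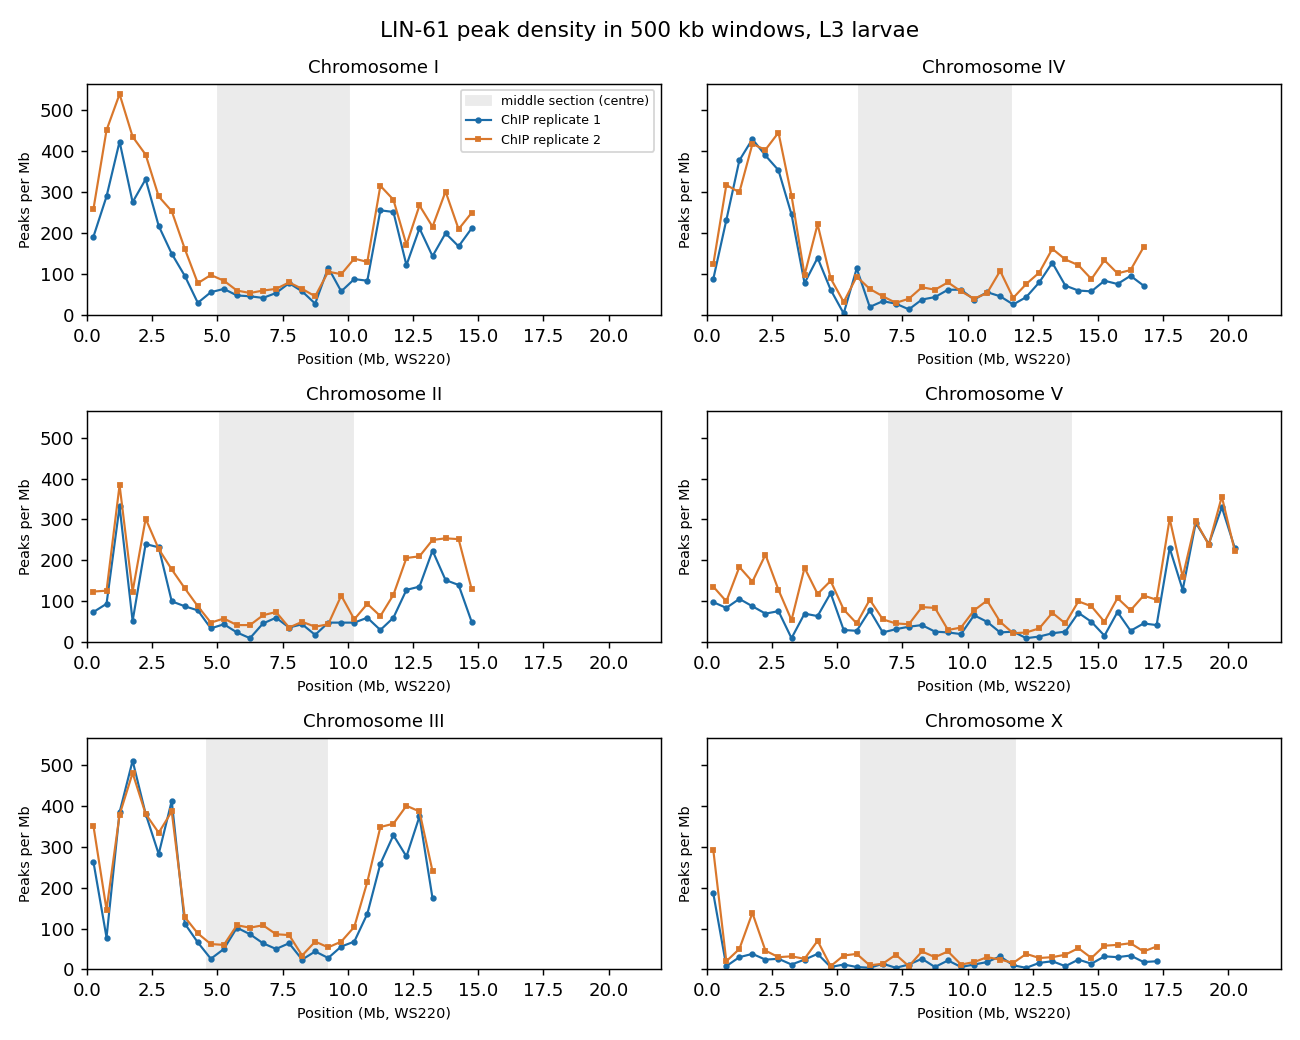
LIN-61 peaks per Mb (y axis) in windows of 500 kb along each chromosome (x axis, position in Mb on WS220) in ChIP replicate 1 (blue) and replicate 2 (orange), with the middle section shaded. The highest windows lie on autosome arms, at 1.5 to 2.0 Mb on III in replicate 1 (510 per Mb) and at 1.0 to 1.5 Mb on I in replicate 2 (540 per Mb). On X the first window is the highest, with 186 and 292 per Mb, and the highest of the other full windows has 38.0 and 138.0.

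Each C. elegans chromosome has its meiotic pairing centre, the site where homologous chromosomes pair and begin synapsis, near one end. The arm holding it was set against the opposite arm. The pairing-centre arm was the denser on III (283 ± 14 against 224 ± 39 peaks per Mb, SD, n = 2) and on X (49.9 ± 22 against 32.7 ± 17). It was also the denser on IV (229 ± 20 against 93.2 ± 30) and on V (148 ± 24 against 94.6 ± 38). On I it was the sparser (200.3 ± 36 against 250.1 ± 63). On X the difference rested on the first 500 kb: without it the left arm had 20.7 peaks per Mb in replicate 1 and 44.2 in replicate 2, against 20.7 and 44.7 on the right arm. On II the arms had 151 ± 29 and 145 ± 44 peaks per Mb, and the replicates differed in sign. The test took the opposite arm on IV and V. With those arms the mean difference was -26.2 peaks per Mb with an SD of 68.6 over the 6 chromosomes. IV and V entered it as -136.1 and -53.1 peaks per Mb, though the true pairing-centre arm was the denser on both. The exact sign-flip permutation test gave p = 0.5 and an adjusted value of 0.5. These values do not decide whether pairing-centre arms were denser, and no test was run with the true ends.

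The X chromosome carried fewer LIN-61 peaks than any autosome in both replicates. It made up 17.7% of the sequence but held 4.11% of the peaks in replicate 1 (409 peaks) and 5.90% in replicate 2 (796 peaks). Peak density on X was 23.1 per Mb in replicate 1 and 44.9 in replicate 2. The autosomes averaged 120.0 ± 40 and 158 ± 42 per Mb (SD, n = 5 autosomes). The ratio of X to the autosome mean was 0.238 ± 0.065 (SD, n = 2). Peaks covered 0.946% of X and 5.25% of the autosomes in replicate 1, and 2.41% against 8.53% in replicate 2. Among the autosomes the order was III, I, IV, II and V in both replicates, from 191 ± 23 peaks per Mb on III to 94.8 ± 26 on V. With X as 1 of 6 chromosomes the exact permutation p was 0.167, the smallest possible, with an adjusted value of 0.208, so this design cannot place X apart from the autosomes by that test. The larvae were of mixed sex and males carry a single X. The share of males and the read coverage of X were not measured here.

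The next comparison asked how far the replicates found the same sites. Of the replicate 1 peaks, 74.7% (7439 of 9958) overlapped a replicate 2 peak. Of the replicate 2 peaks, 47.1% (6358 of 13486) overlapped a replicate 1 peak. Random circular shifts gave 13.7% ± 1.9 and 9.5% ± 1.3 (SD over 10000 shifts), so the observed shares were 5.43 and 4.97 times the chance level. Both had a one-sided permutation p of 0.0001, the smallest that 10000 shifts can give. Random placement within the same sections, which keeps the arm bias, gave 18.9% and 11.9%. When at least 50% of both peaks had to be covered, the shares fell to 34.9% and 25.8%. The lists had 3.21 Mb in common, 74.4% of the bases in replicate 1 peaks and 44.4% of those in replicate 2 peaks.

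Sharing rose with peak score in both lists. In replicate 1, 97.5% of the highest-scoring 25% (95% interval 96.8 to 98.1) and 53.3% of the lowest (51.3 to 55.2) were found in replicate 2. In replicate 2, 83.0% of the highest-scoring 25% (81.7 to 84.3) and 24.3% of the lowest (22.8 to 25.8) were found in replicate 1. Under a reciprocal overlap of 50% these shares were 64.2% and 15.2% in replicate 1, and 50.3% and 10.4% in replicate 2. In replicate 2 the shared peaks had a median width of 477.5 bp and the others 248.0 bp, and wider peaks meet a 1 bp overlap more easily. Across peaks, the scores of overlapping peaks had a Spearman's rho of 0.467 over 7439 replicate 1 peaks and 0.550 over 6358 replicate 2 peaks; peaks are not independent replicates, so no p is given. The rho was 0.719 over the 3480 pairs of peaks with a reciprocal overlap of 50%.

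**Figure D3:**
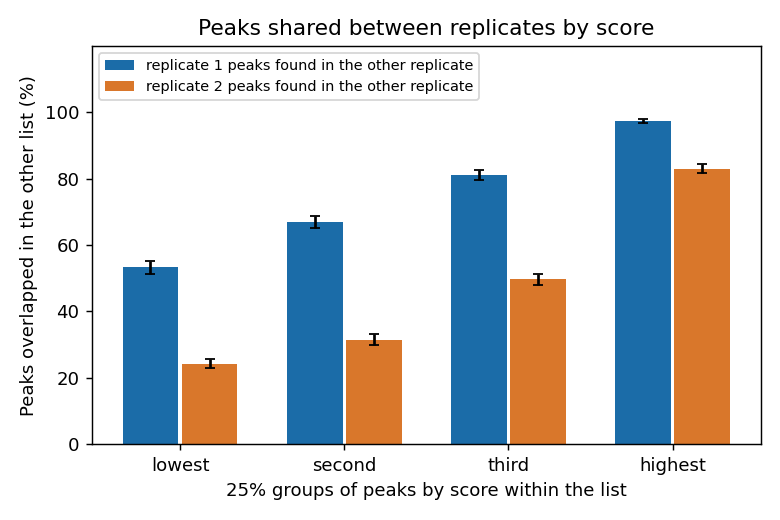
Percentage of peaks overlapped by at least 1 bp in the other replicate (y axis) for successive groups of 25% of each list ordered by score (x axis), for ChIP replicate 1 (blue) and replicate 2 (orange). Error bars are exact 95% binomial intervals; the share climbs from 53.3% to 97.5% in replicate 1 and from 24.3% to 83.0% in replicate 2.

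More peaks of the authors' whole-series list overlapped replicate 2, the longer list, than replicate 1. Of its 14662 peaks, 37.2% (95% interval 36.4 to 38.0) overlapped peaks of both replicates, 39.1% (38.3 to 39.9) of replicate 2 alone and 9.46% (8.99 to 9.95) of replicate 1 alone. A further 14.3% (13.7 to 14.9), or 2096 peaks, overlapped no peak of either replicate. The median score was 20.4 for peaks found in both replicates and 3.71 for those found in neither. In turn, 91.4% of the replicate 1 peaks and 95.4% of the replicate 2 peaks overlapped a peak of the whole-series list. Under a reciprocal overlap of 50%, 17.99% were found in both replicates and 24.5% in neither.

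LIN-61 peaks lay closer together than peaks placed at random within the same sections. The placement is even within a section, so broad changes in density inside a section can add to the excess. They were not separated from local clustering. In replicate 1, 90.1% of peaks had another within 5 kb, against 74.1% ± 0.4 (SD over 1000 placements) for the same peaks placed at random within the same sections. In replicate 2 the values were 89.5% and 80.9% ± 0.3. Both had a one-sided permutation p of 0.001, the smallest that 1000 placements can give. The excess was larger at a distance of 1 kb (43.7 and 35.9 percentage points) than at 5 kb (16.07 and 8.57), and at 20 kb it was 0.6 in replicate 1 and -0.6 in replicate 2. In the higher-scoring 50% of each list the excess at 5 kb was 26.0 and 15.3 percentage points. The observed shares fell there to 82.0% and 78.6%, and the random ones fell further, to 56.0% and 63.3%. The peak caller itself can break a broad region into neighbouring peaks; with peaks less than 500 bp apart merged, the observed shares fell to 80.4% and 78.9% and the random ones to 58.7% and 67.9%, an excess of 21.7 and 11.02 percentage points. The longest stretch shared by both replicates ran for 150.8 kb on the left arm of chromosome III, from position 1468456 to 1619222, with 117 peaks in replicate 1 and 94 in replicate 2. The next 3 stretches were also on III, spanning 90.0 kb (12538373 to 12628381), 88.4 kb (1791560 to 1879982) and 81.1 kb (1152194 to 1233318), followed by 65.0 kb on the left arm of I (2001658 to 2066675).

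Of the 10 highest-scoring peaks of the whole-series list with support in both replicates, 7 lay in the left arm of chromosome III, and 1 each on the left arm of X, on the left arm of IV and in the centre of II. The highest was on X at 188052 to 191474, with a score of 214.0 in the authors' list; its best overlapping peak scored 80.2 in replicate 1 and 206.5 in replicate 2. The second was on IV at 2254577 to 2263480, with a score of 212.3. On III the peaks at 1615130 to 1617366 and at 1512875 to 1523691 scored 209.2 and 206.0. The remaining peaks on III lay at 2146142 to 2151747 (score 202.7), 2836235 to 2838003 (194.9), 1606921 to 1610396 (193.8), 1934531 to 1943313 (193.8) and 1898608 to 1901208 (186.0). The peaks at 1615130, 1512875 and 1606921 lie within the 150.8 kb stretch of dense peaks. The peak in the centre of II, at 10174382 to 10175000, was the narrowest of the 10, at 619 bp, and scored 195.7. It lay close to the right boundary of the middle section, at 10186230. With a reciprocal overlap of 50% required, 6 of the 10 kept support in both replicates. The genes at these positions were not analysed here.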

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

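Threshold calls here refer to unadjusted p-values. Several p-values stand at the smallest value their test can give, so an unchanged call there does not show a stable size: the shares of replicate 1 and 2 peaks found in the other list (74.7% and 47.1%) became 34.9% and 25.8% under reciprocal overlap with p = 0.0001 in the permutation test under both rules. The arm-to-centre contrasts of density, width and score had p = 0.03125 in the exact permutation test under each alternative run, and without replicate 1 or 2 the density difference was 123.3 and 96.9 peaks per Mb. The X-to-autosome ratio ranged from 0.192 to 0.284 with a replicate left out, and was 0.206 in the higher-scoring 50%. Peaks with scores tied at that cut were kept in order of chromosome, with X last, which can lower that ratio. The contrast of the arms taken as pairing-centre arms, with the opposite arm taken on IV and V, stayed negative and unsupported. It ran from -7.27 peaks per Mb in the higher-scoring 50% to -40.3 with arms as the outer 25%. With a replicate left out it ran from -30.7 to -21.7. Because of the arms taken on IV and V it does not bear on pairing centres. The reversal was the clustering excess of replicate 2 at 20 kb, -0.58 percentage points; at that distance 98.0% of randomly placed peaks already have a neighbour, so the measure is near its ceiling. Peaks of the whole-series list found in both replicates (37.2%) became 17.99% under reciprocal overlap, 26.0% under the midpoint rule and 40.8% in the higher-scoring 50%; those in replicate 2 alone became 47.6%, 45.6% and 38.2%, and those in neither 24.5%, 17.8% and 12.3%. Those in replicate 1 alone became 10.6% under the midpoint rule and 8.69% in the higher-scoring 50%. Spearman's rho rose to 0.719 from either list under reciprocal overlap; the cause was not tested. With peaks less than 500 bp apart merged, 6168 and 8555 peaks remained, numbers added after seeing the data. No paired analysis was possible because the ChIP and input libraries share replicate numbers but only peak lists of the ChIP libraries were analysed here. The gene location and gene list alternatives were not run. Unknown read depth limits any reading of the difference in peak number between the replicates, and with 2 replicates a permutation test of single regions cannot reach a p under 0.05.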

Other observations

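The tests on merged peaks and on X compared within arms and centres were chosen after the values they use had been seen; the tests by score group and of the peaks found only in replicate 2 were fixed before. The values in the next 2 paragraphs were picked out after seeing the data.

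Peaks on X were gathered at its left end. The first 500 kb of X, 2.82% of the chromosome, held 93 of its 409 peaks in replicate 1 (22.7%, exact 95% interval 18.8 to 27.1) and 146 of 796 in replicate 2 (18.3%, 15.71 to 21.21). The density there was 186 and 292 peaks per Mb, against medians of 17 and 33 in the 34 other full windows of X and maxima of 38.0 and 138.0. The median score was 12.9 inside this window and 5.59 in the rest of X in replicate 1, and 10.0 against 6.17 in replicate 2. The highest-scoring named peak lies in this window. Without the window the X arms held 20.7 and 44.5 peaks per Mb, against 13.9 and 24.9 in the X centre. The left end of X also holds the X pairing centre. Among the autosomes the pairing-centre arm was the denser on III, IV and V and the sparser on I, and on II the replicates differed in sign. A link between peaks and pairing centres was not tested.

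The left arms of chromosomes III and II held a larger share of the high scores than of all peaks. The left arm of III held 36.7% of the top-scoring 5% of peaks in replicate 1 (183 of 498) and 29.2% in replicate 2 (197 of 675), but 12.6% and 9.97% of all peaks. The left arm of II held 17.5% and 12.7% of the top-scoring 5%, and 6.68% and 6.47% of all peaks. On chromosome V, the 6 full windows from 17.5 Mb onwards held 128 to 330 peaks per Mb in replicate 1 and 160 to 356 in replicate 2, against medians of 42.0 and 84.0 and maxima of 120.0 and 214.0 over the windows before it, so that the ranges overlapped in replicate 2. The last, partial window of V, from 20.5 Mb, had 47.2 and 96.7 peaks per Mb. Over the 197 full windows of 500 kb in the genome, the densities of the replicates had a Spearman's rho of 0.941, across windows that are not independent.

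For the excess of peaks on the arms, splitting of bound regions into several calls would bring the fold of peak density near 1 once neighbouring peaks are merged. Merging peaks less than 500 bp apart left a fold of 2.95 ± 0.16 (SD, n = 2), against 3.27 ± 0.23 before, which argues against splitting at such distances as the whole cause. An excess of weak peaks near the calling threshold would give the larger fold among low scores. The fold was instead 2.83 times higher in the highest-scoring 25% than in the lowest (7.86 against 2.60 in replicate 1, 5.74 against 2.18 in replicate 2). Repeated sequence that attracts reads in any library stays open, because input libraries and repeat annotation were not used here, and so does the hypothesis of binding to the arms, which are rich in methylated H3K9 chromatin.

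For the shortage of peaks on X, a larger share of centre-like sequence on X was considered. The density on the X arms was 0.331 times that of the lowest autosome (0.279 and 0.383). This does not decide, because sections were set by length and arms of centre-like sequence would also be sparse. The X arms held 27.7 and 54.9 peaks per Mb, against 30.1 and 54.1 in the lowest autosome centre. The X centre was also below every autosome centre, at 0.461 and 0.460 times the lowest, which argues against that explanation as the whole cause. Weak peaks falling under the threshold stay open. The X-to-autosome ratio was 0.199 in the highest-scoring 25% (0.184 and 0.213) and higher in the lowest-scoring 25% (0.255 and 0.345). Scores lowered along all of X would also remove X peaks from the highest group. This test therefore does not decide, and the limit set for it beforehand was wrong. A real difference in binding was not tested.

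For the 7128 replicate 2 peaks with no overlapping peak in replicate 1, lower sensitivity of the replicate 1 library is a candidate explanation. It predicts that sharing rises with score, and the highest-scoring 25% were shared 58.7 percentage points more often than the lowest-scoring 25%. Spurious weak peaks in replicate 2 predict the same and stay open. A different division of binding between arms and centres was also considered. Of the peaks found only in replicate 2, 83.0% lay on the arms, against 89.7% of the shared ones. Most of the unshared peaks were thus not in the centres. The difference of -6.66 percentage points (95% normal interval -7.80 to -5.51, counting error only) lies within the limit of 10 set beforehand. A shift towards the centres, smaller than that limit, is in these values. Weak peaks were also less concentrated on the arms. In replicate 2 the arm-to-centre fold was 2.18 in the lowest-scoring 25% and 5.74 in the highest. The arm share thus mixes score with place, and this test does not decide. The arm share cannot show shifts between chromosomes or between arms, so those stay open.

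Chosen after seeing the data, the left ends were also counted. A peak lay in the first 500 bp of 5 of the 6 chromosomes in replicate 1 (not III), of 4 in replicate 2 (not III or IV) and of 6 in the authors' whole-series list. Random placement within the same sections put a peak on 0.476 and 0.652 left ends on average in replicates 1 and 2, and on at most 4 in either; it does not keep the clustering of the peaks, and no p is given because the ends were chosen for their peaks. The right ends were left out because the last peak defines them here.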
